A study of Mus musculus with 2 samples.

How the data were processed

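Gene expression was measured on oligonucleotide arrays in gonad-mesonephros complexes, the embryonic gonad with its attached mesonephric kidney, dissected from XX mouse embryos at embryonic day 12.5 (E12.5). One array held RNA of wild-type complexes and one held RNA of complexes homozygous for the Gata4ki allele. Per the labels' protocols, each array carried total RNA from 6 pairs of complexes, converted to biotin-labelled cRNA. The strain was stated for the mutant only (C57Bl/6). With 1 array per group, no p-value, standard deviation or test between groups could be given, and every difference describes these 2 arrays.

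The deposited values are signal intensities per probe set on a linear scale, made with MAS5 per the submitters' processing notes. The MAS5 version, the detection calls and any filter on probe sets are not given in the sources used here. The values show the MAS5 global scaling, since the mean without the top and bottom 2% of probe sets was 150.0 on both arrays. The 45101 probe sets ranged from 0.0373 to 14150 on the wild-type array and from 0.0349 to 14121 on the mutant array. The median signals were 24.1 and 24.0, and the 75th percentiles were 152.8 and 152.6. Scaling by 1 factor per array leaves the ratios between genes on an array as they were. Such values are least precise at low signal, where background subtraction dominates. The number of arrays and the signal over background limit the precision, and no counting interval applies.

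Probe sets were named through the platform's annotation table. Of the 45101 probe sets, 34958 had 1 gene symbol, 932 had several and 9160 were not listed and stay unnamed here. The 64 control probe sets, some of which carry a gene symbol in that table, took no part in the gene comparisons. For 34754 of the probe sets with 1 symbol the gene number was found in the RefSeq gene table of assembly GRCm38.p6, which changed no symbol. No genome build is named for the array values, so no coordinates are given.

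The values were used as deposited, with no further normalization. A floor was set at the 50th percentile over both arrays, a signal of 24.0; lower values were set to it before taking log2. A gene was measured where at least 1 array was above the floor, and a ratio with 1 array at or under it is a bound, written as "at least". A gene was represented by its probe set with the highest mean log2 signal. Log2 ratios are mutant minus wild type. Genes at least 2-fold apart were counted. Genes whose measured probe sets, 2 or more, were all at least 2-fold apart the same way were counted separately, beside 100 random reassignments of probe sets to genes. Probe sets of a gene read the same RNA sample, so their agreement shows probe noise and not the spread between embryos.

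The 31 gene lists, the floor, the alternatives and the rule for named genes were fixed before the data were examined. The lists cover gonadal, germ cell, mesonephric and signalling genes, and markers of other cell types or neighbouring tissues. They were written from general knowledge of the field, in which Dkk1 and the ovarian markers were already known as genes of interest for this mutant. For each list with at least 4 measured genes, the median log2 ratio was placed among the medians of 10000 random lists of the same size, matched on mean signal in 20 bins. A list was said to stand apart at or under percentile 2.5 or at or above 97.5. The percentile treats genes as independent, which genes of 1 cell type are not, and describes these 2 arrays only. The error given for a list median is the SD over 1000 bootstrap resamples of its genes. The rule named Gata4 and Zfpm2; the 15 highest and 15 lowest ratios among genes above the floor on both arrays, with no measured probe set pointing the other way and leaving out clone and predicted-gene names; the 5 largest bounds each way; up to 4 genes per list with the largest absolute ratios; and Wnt4, Fst, Foxl2, Dkk1, Sox9, Amh, Star, Stra8, Nr5a1 and Wt1 in any case. Other genes are named where they complete a group or a count, and were chosen after their values were seen. Another 3 marker lists, for trophoblast, pancreas and granulocytes, were added after Ctsj, Ctsq, Prl2b1, Cpa1, Mpo and Prg2 had been seen among the most changed genes, and those 6 genes were kept out of them.

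The procedure was tested on a simulated pair of arrays for the comparison of mutant and wild type. Noise was normal, with the robust SD of the ratios at each signal level. There were 12084 measured genes and 200 changed genes, the changed ones all with a mean signal above 4 times the floor. The procedure recovered 98 of 100 genes changed by 1.5 on the log2 scale, 50 of 50 changed by 2.0 and 50 of 50 changed by 3.0. It called 21 unchanged genes 2-fold apart, which may be too few, since normal noise can lack the tails of real arrays. Of 200 random lists of unchanged genes, 11 stood apart, or 5.5%, and 20 of 20 lists shifted by 0.5 did. The random lists held independent genes, so the 5.5% does not cover genes that vary together. The alternatives tried were median centring, quantile normalization, an intensity-dependent loess with a span of 0.3, floors at the 40th and 60th percentile, no floor with a pseudocount, the median over a gene's probe sets, leaving out suffixed probe sets, a 3-fold threshold, and each list without its most changed gene. Suffixed probe sets are those whose identifier ends in _x_at, _s_at or _a_at. The endings _x_at and _s_at mark possible cross-hybridization, whereas _a_at marks probes shared by transcripts of 1 gene. The percentile of each list under these alternatives was added after the data were seen. The software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.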

Results

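Transcript levels were compared between gonad-mesonephros complexes of XX wild-type embryos and of XX embryos homozygous for Gata4ki, both at E12.5. GATA4 is a zinc finger transcription factor of the somatic gonad. The Gata4ki allele is a knock-in that weakens binding of GATA4 to its FOG cofactors, and the comparison asks which genes in the developing ovary depend on that complex. Each group consisted of 1 array hybridised with RNA of 6 pairs of complexes, so no replicate error exists for any value below. Of 18193 genes represented on the array, 12300 were above the floor on at least 1 array and 11462 on both. The wild-type array had 22566 probe sets above the floor and the mutant array 22534.

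The embryos' sex and the added control RNAs were examined first. Xist, the RNA expressed from the inactive X chromosome, gave signals of 1805 and 1742 on its brightest probe set in wild type and mutant. The Y-linked genes Eif2s3y, Kdm5d and Uty, and Sry, were not above the floor on either array. The 42 probe sets for added bacterial control RNAs had a median log2 ratio of 0.01 ± 0.18 (SD over probe sets). The ratio of 3' to 5' signal was 2.16 in wild type and 2.47 in the mutant for beta-actin, and 0.90 and 1.10 for Gapdh.

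Most genes had similar signals on both arrays, and a small set of named genes stood far apart. Follistatin (Fst), Sprr2d, Gng13 and Foxl2 were among the genes with the largest deficits in the mutant. Cpa1, Dkk1, Cyp17a1 and Hsd3b1 were among those with the largest excess. In all, 104 genes were at least 2-fold higher in the mutant and 66 at least 2-fold lower, 1.38% of the measured genes, while 93.3% lay within 1.5-fold with bounds taken at their value. Of these, 41 of the higher and 17 of the lower genes had 1 array at or under the floor. Moving the floor to the 40th or 60th percentile changed these counts to 210 and 136 or to 41 and 33. The robust SD of the log2 ratio across probe sets was 0.37 at mean signals under 100, 0.22 from 100 to 400 and 0.12 above 400. Among 5463 genes with at least 2 measured probe sets, 9 had every probe set at least 2-fold apart the same way. Dkk1, Vsnl1, Fcgr2b, Thbs2, Prl2b1, Plaat3, Car4 and Vnn1 were higher in the mutant and Fst was lower. Random assignment of probe sets to genes gave means of 0.16 higher and 0.17 lower genes, and at most 2 of either.

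**Figure D1:**
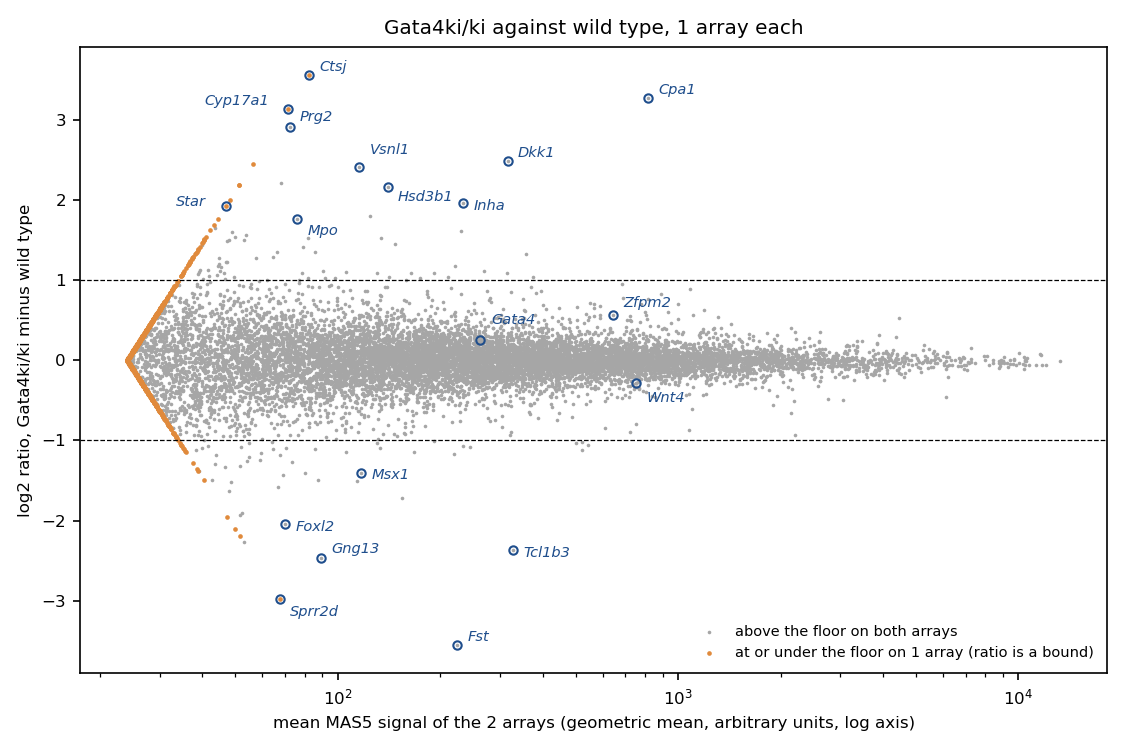
Each point is 1 of 12300 measured genes, with the geometric mean MAS5 signal of the 2 arrays on a log axis and the log2 ratio of Gata4ki/ki over wild type on the vertical axis. Dashed lines mark 2-fold differences and orange points are bounds; Fst lies at -3.55, Dkk1 at 2.48 and Gata4 at 0.25.

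Both Gata4 probe sets were within 1.5-fold between the arrays, and both FOG genes had higher signals in the mutant. Gata4 gave signals of 240.8 in wild type and 286.2 in the mutant on its brightest probe set, a log2 ratio of 0.25, whereas its dimmer probe set gave 49.2 and 34.6, a ratio of -0.51. The 2 probe sets disagreed in sign, and since the allele alters the protein, these values do not check the labels. Zfpm2, which encodes FOG2, had signals of 530.2 and 784.0, a log2 ratio of 0.56, and its second probe set had a ratio of 0.97. Zfpm1, which encodes FOG1, was 2.06-fold higher, with a log2 ratio of 0.96 when a pseudocount replaced the floor. Gata2 was 1.33-fold higher, and Gata6 had a log2 ratio of 0.03. Of the 8 GATA and FOG genes, 1 was 2-fold higher and none 2-fold lower. Their median log2 ratio was 0.22 ± 0.15 (bootstrap SD), at percentile 98.2 of random lists, and at percentile 88.8 with the median over each gene's probe sets. Erythroid and macrophage genes had medians of 0.96 and 0.53 on the same array.

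Genes of the ovarian supporting cells were the list with the lowest median. Fst, which encodes an activin-binding protein expressed in the early ovary, was 11.7-fold lower in the mutant, with signals of 769.5 and 65.6. Its second probe set gave 241.9 and 25.2. Foxl2, a forkhead transcription factor of the granulosa lineage, was 4.13-fold lower, with signals of 142.4 and 34.5. Gng13, a G protein gamma subunit, was 5.51-fold lower and Sprr2d, a small proline-rich protein, at least 7.87-fold lower. The homeobox genes Msx1 and Irx3 were 2.66-fold and 2.09-fold lower. The second probe set of Msx1 gave a log2 ratio of -0.50 or lower, with the mutant array under the floor. Of the 16 measured genes in this list, 6 were at least 2-fold lower, none was 2-fold higher, and the other 10 did not reach 2-fold at this floor, Irx5 (33.9 and 23.9) being known only as a bound of -0.49.

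Other ovarian genes of the same list did not reach 2-fold. Wnt4, a WNT ligand required for ovarian development, had signals of 829.1 and 680.7 and a log2 ratio of -0.28. Its second probe set gave a ratio of -0.43. Each array read gonad and mesonephros together, so a ratio does not give the change in the gonad alone. Rspo1, a secreted WNT agonist, and Bmp2 had log2 ratios of 0.34 and 0.42. Lgr5 had a ratio of 0.62 and Cdkn1b, a cell cycle inhibitor, of -0.89. The list median was -0.52 ± 0.35 (bootstrap SD) and lay below the medians of all 10000 random lists. It was -0.49 without its most changed member, Fst. The ovarian markers were already known as genes of interest for this mutant when the list was written. Its place among random lists is therefore not independent support. On the same mutant array, macrophage and erythroid genes had medians of 0.53 and 0.96.

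**Figure D2:**
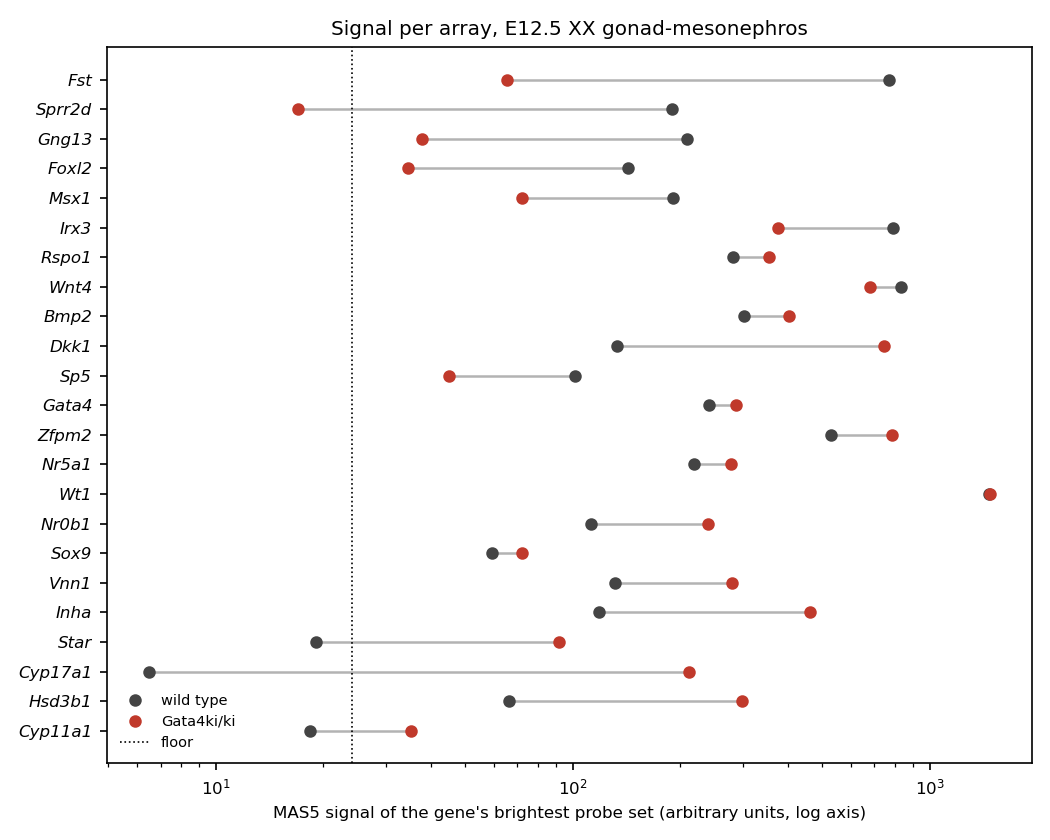
Signal of each gene's brightest probe set on the wild-type array (grey) and the Gata4ki/ki array (red), on a log axis in arbitrary units, with the floor of 24.0 dotted. Fst is at 769.5 and 65.6 and Dkk1 at 133.4 and 746.3, while Wt1 is at 1461 and 1475.

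Genes that establish the early gonad, and the testis pathway, showed few differences. Wt1 had signals of 1461 and 1475, Nr5a1, which encodes steroidogenic factor 1, of 218.7 and 276.7, and Lhx9 of 1890 and 1629. Nr0b1, an orphan nuclear receptor, was 2.13-fold higher in the mutant, and Numb was 1.39-fold lower. The 11 measured early gonad genes had a median log2 ratio of -0.03 ± 0.14, at percentile 29.2. In the Sertoli and testis list, Sox9 had signals of 59.3 and 72.1 and a log2 ratio of 0.28, and Amh was not above the floor on either array. Vnn1 was 2.13-fold higher, with both probe sets at least 2-fold apart, whereas Dmrt1 and Aard had ratios of -0.71 and -0.55. Cst9 was at least 1.40-fold lower. Of the 10 measured genes of this list, 1 was 2-fold higher and none reached 2-fold lower at this floor, while Cst9 reached -1.30 with a lower floor. The median was -0.05 ± 0.27, at percentile 25.8. Without its most changed gene, Vnn1, this median was -0.27, at percentile 1.2.

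Steroidogenic genes formed the list with the highest median. Cyp17a1, which encodes the enzyme for androgen precursors, had signals of 6.49 in wild type and 211.8 in the mutant and was at least 8.81-fold higher. Hsd3b1, a hydroxysteroid dehydrogenase, was 4.49-fold higher, with 66.1 and 297.0. Star, the cholesterol carrier of mitochondria, was at least 3.82-fold higher on its brightest probe set, while its other probe sets gave log2 ratios of at least 0.91 and of 0.17. Cyp11a1, the side-chain cleavage enzyme, was at least 1.46-fold higher at a mutant signal of 35.2. Fdx1 and Scarb1 had log2 ratios of 0.03 and -0.25. Of 6 measured genes 3 were 2-fold higher, and the median log2 ratio was 1.24 ± 0.79 with bounds taken at their value, above all 10000 random lists. Across the alternative settings this median ranged from 0.55 to 1.93. Inha, the inhibin alpha subunit, was 3.89-fold higher, with 118.6 and 461.7. Among adrenal cortex genes, Cyp21a1 and Cyp11b1 were not above the floor on either array, Mc2r had a log2 ratio of 0.32 and Mrap a bound of 0.52. On the same array macrophage and erythroid genes had medians of 0.53 and 0.96. The trophoblast list had a median of 0.31 (percentile 99.6), which is the ratio of Rhox6, a gene already bright in wild type (398.9 and 493.8). Of its 9 measured genes 1 was at least 2-fold higher, Prl7d1 with signals of 3.20 and 54.8. Peg10, Hand1 and Tfpi2 had ratios of 0.11, at least 0.04 and -0.10. Ctsj, with 1.29 and 282.6, and Prl2b1, with 0.64 and 131.9, were kept out of that list because they had been seen high.

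WNT and activin pathway genes went both ways within their lists. Dkk1, a secreted WNT antagonist, had signals of 133.4 and 746.3, a log2 ratio of 2.48, and its second probe set gave 52.2 and 198.7. None of the other 9 measured WNT antagonists reached 2-fold at this floor, with Sfrp5 known only as a bound of -0.16. Dkk3 had a ratio of -0.69 on its brightest and 0.42 on its other probe set, Kremen1 of -0.47 and Sfrp4 of 0.40. The list median was -0.21 ± 0.17, at percentile 1.01, opposite in sign to Dkk1, and lay at percentile 3.88 with the median over each gene's probe sets. Of 11 WNT feedback targets, Sp5 was 2.26-fold lower, though just under 2-fold when a pseudocount replaced the floor. Rnf43 and Lef1 had ratios of -0.72 and -0.54, whereas Axin2, a general readout of WNT signalling, had a ratio of 0.13. Their median was -0.05 ± 0.17, inside the central range of random lists from -0.15 to 0.15. Among 14 BMP and activin genes, Fst was 2-fold lower and Inha 2-fold higher. Id4 had a ratio of -0.82, and Bmp2 and Bmp4 had ratios of 0.42 and 0.36. The median was -0.22 ± 0.13, below all 10000 random lists, and -0.13 at percentile 0.98 when a pseudocount replaced the floor.

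No germ cell or meiotic gene reached a 2-fold difference at this floor, with Gtsf1, Hormad1, Sycp1 and Zglp1 known only as bounds. Dazl had signals of 580.8 and 467.0, Ddx4 of 296.8 and 255.8, Pou5f1 of 180.5 and 196.8, and Dppa5a of 1868 and 2476. Tfap2c had the largest ratio among the 20 measured germ cell genes, 0.92, or 0.13 without suffixed probe sets, followed by Dnd1 at -0.71, Kit at 0.51 and Alpl at -0.51. The germ cell median was -0.01 ± 0.10, at percentile 36.0. Stra8, which marks entry into meiosis, was not above the floor on either array. Among the 10 measured meiotic genes, Rec8, a meiotic cohesin, was 1.92-fold lower with 206.5 and 107.4, and Stag3, Smc1b and Msh5 had ratios of -0.27, -0.29 and 0.33. The meiotic median was -0.03 ± 0.11, at percentile 32.9.

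Markers of the mesonephros and of other cell types described the tissue on each array. Calb1, Wnt7a and Amhr2, genes of the mesonephric and Müllerian ducts, had log2 ratios of -0.72, -0.63 and -0.51, and Cdh6 had 0.43. The 14 duct and tubule genes had a median of -0.15 ± 0.10, at percentile 2.09, or 3.49 without the most changed gene. Among 17 endothelial genes 13 had a ratio below 0, with Sox17, Sox18, Tek and Cdh5 at -0.66, -0.57, -0.44 and -0.38 and a median of -0.18 ± 0.07 (percentile 0.44, or 4.94 without suffixed probe sets). Coelomic epithelium genes had a median of 0.20 ± 0.10 (percentile 99.9, or 96.3 without suffixed probe sets), with Krt8, Krt7, Muc16 and Krt19 at 0.43, 0.40, 0.40 and 0.29. Stromal genes had a median of 0.03 ± 0.07 (percentile 83.5). Acta2, smooth muscle actin, had a ratio of 0.89, and Col1a1, Pdgfrb and Maf had 0.38, 0.32 and -0.28. No gene of these 4 lists was 2-fold apart.

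The erythroid and macrophage lists had median ratios above 0, though most of their genes did not reach 2-fold at this floor. Of 9 measured erythroid genes 4 were at least 2-fold higher. Hemgn was at least 4.57-fold, Klf1, an erythroid transcription factor, 3.15-fold, Slc4a1 2.67-fold and Alas2 2.04-fold higher. Of these genes 3 each no longer reached 2-fold in an alternative setting. Klf1 had a bound of 0.67 at the 60th percentile floor, Slc4a1 a log2 ratio of 0.95 without suffixed probe sets and Alas2 one of 0.92 with the pseudocount. The embryonic globins were close, with Hba-x at 3964 and 4840. The erythroid median was 0.96 ± 0.45, above all 10000 random lists. It was 0.63 without its most changed gene, Hemgn, and 0.63 with the floor at the 40th percentile. Of 16 macrophage and leukocyte genes, 14 had a ratio above 0 and 1 was 2-fold higher. Mpo, myeloperoxidase, was 3.40-fold higher, and Ptprc, Fcer1g and Csf1r had ratios of 0.92, 0.87 and 0.77. Their median was 0.53 ± 0.12, also above all 10000 random lists.

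No gene of the liver, gut, kidney, neural and skeletal muscle lists reached 2-fold at this floor, though several are known only as bounds. Skeletal muscle genes stood apart on the low side. The liver gene Afp had a ratio of -0.47 and Apoa2 a bound of 0.33 that reached 1.08 with a lower floor, and 2 of 10 liver genes on the array were measured. The gut genes Shh, Vil1 and Cdx2 had ratios of -0.70, at most -0.43 and at most -0.01. Kidney genes had a median of 0.10 ± 0.18 (percentile 69.6), with Hoxa11 at -0.59 or lower (-1.02 with a lower floor), Slc34a1 at 0.58, Six2 at 0.42 or higher and Foxd1 at 0.34. Neural genes had a median of -0.01 ± 0.11 (percentile 40.1), with Chga, Phox2a and Erbb3 at -0.90, -0.47 and 0.20, and Elavl4 at 0.28 or higher. Skeletal muscle genes had a median of -0.35 ± 0.14 (percentile 1.97, or 11.3 with the floor at the 60th percentile), with Myl1, Des and Actc1 at -0.38, -0.38 and -0.35 and Tnni1 at 0.23.

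**Figure D3:**
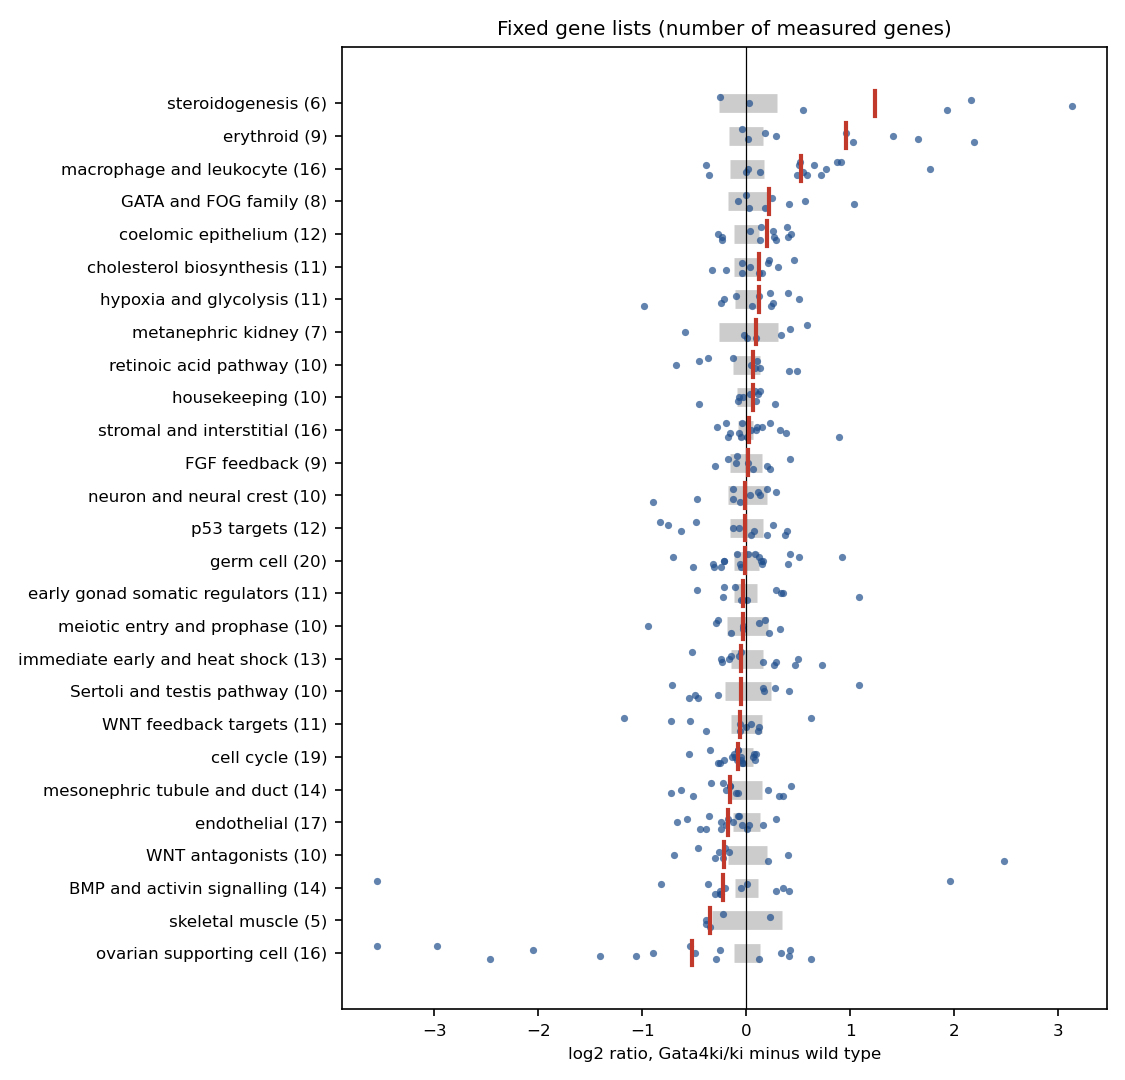
Log2 ratio of Gata4ki/ki over wild type for the measured genes (points) of the 27 lists with a percentile, with the list median (red line) and the range holding the central 95% of random list medians (grey band). The ovarian list median is -0.52 and the steroidogenesis median 1.24.

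In the remaining lists no gene reached 2-fold at this floor, but Eda2r, Etv4, Atf3, Tyms and Fos are known only as bounds, and with a lower floor Eda2r, Etv4 and Atf3 reached -1.28, -1.02 and 1.09. Cell cycle genes had a median of -0.08 ± 0.03 (percentile 1.11), with Mcm4, Plk1 and Ccne1 at -0.35, -0.27 and -0.25 and Tyms at -0.55 or lower. Hypoxia and glycolysis genes had a median of 0.12 ± 0.13 (percentile 98.3, or 89.0 with the median over each gene's probe sets). In that list Pfkfb3, Egln3 and Aldoa were at 0.51, 0.41 and 0.26, while Adm, adrenomedullin, was at -0.98. Cholesterol synthesis genes had a median of 0.13 ± 0.08 (percentile 97.4), with Idi1, Msmo1, Nsdhl and Lss at 0.46, 0.31, 0.22 and -0.33. Retinoic acid genes had a median of 0.07 ± 0.15 (percentile 83.2), with Aldh1a3, Aldh1a1, Crabp1 and Cyp26b1 at -0.67, 0.49, -0.45 and 0.41. FGF feedback genes had a median of 0.02 ± 0.11 (percentile 60.3), with Il17rd, Dusp6 and Spry1 at 0.42, 0.23 and 0.20 and Etv4 at -0.29 or lower. p53 targets had a median of -0.01 ± 0.19 (percentile 39.2), with Cdkn1a, Bbc3 and Sesn2 at -0.75, -0.62 and -0.48 and Eda2r at -0.83 or lower. Immediate early and heat shock genes had a median of -0.04 ± 0.17 (percentile 23.3), with Ier2 at -0.52, Zfp36 at 0.50, Atf3 at 0.73 or higher and Fos at 0.47 or higher. Housekeeping genes had a median of 0.06 ± 0.05 (percentile 94.9), with Actb, Polr2a, Hprt and Gusb at -0.46, 0.28, 0.13 and 0.11. The measured probe sets of Actb, Aldoa, Cdh6, Cdkn1a, Col1a1, Egln3, Gata6, Gusb, Kit, Lhx9, Lss and Wnt7a did not all point the same way, and Actb had a ratio of 0.20 on its dimmer one. In all, 13 of 27 lists stood apart, 7 low and 6 high, where 1.35 would by chance if genes were independent. The ovarian, BMP and activin, cell cycle, steroidogenesis, erythroid and macrophage lists stood apart in all 9 alternative settings, and the other 7 lists did not. Some lists share genes, such as Fst and Bmp2 in the ovarian and the BMP and activin lists.

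Many of the most changed genes lay outside these lists. Cpa1, carboxypeptidase A1, had the largest excess among genes above the floor on both arrays, 9.69-fold, with signals of 262.7 and 2547. Prg2, the eosinophil major basic protein, was 7.53-fold, Vsnl1, a neuronal calcium sensor, 5.34-fold, and Fcgr2b, an inhibitory Fc receptor, 4.65-fold higher. Thbs2, thrombospondin 2, was 3.48-fold higher on a probe set that can cross-hybridise, and its log2 ratio was 2.59 without such probe sets. Mfap3l was 3.07-fold, Zc3h6 3.04-fold, Tmem184a 2.97-fold, Pcdh20 2.89-fold and Lgals3, galectin 3, 2.89-fold higher, but other probe sets of Mfap3l and Pcdh20 went down to log2 ratios of 0.52 and 0.54. Ctsj and Prl2b1, a cathepsin and a prolactin family hormone of the placenta, had mutant signals of 282.6 and 131.9 against 1.29 and 0.64 in wild type, at least 11.8-fold and 5.49-fold higher. The dimmer probe set of Prl2b1, with 0.17 and 54.5, gave a log2 ratio of at least 1.18. Ccl24, an eosinophil-attracting chemokine, was at least 4.56-fold higher.

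Among the lower genes outside the lists, Tcl1b3 was 5.17-fold lower, with signals of 746.2 and 144.3 on a probe set that can cross-hybridise with relatives. Akr1c14, an aldo-keto reductase acting on steroids, was 4.83-fold, Plxdc1 3.81-fold, Cfap161 3.74-fold and Lgals7, galectin 7, 3.29-fold lower. Ccdc182 was 2.98-fold, Tgfa 2.85-fold, Trim13 2.83-fold, Sars2 2.82-fold, Rpl39 2.81-fold and Trank1 2.70-fold lower. Slitrk1, Stum, Rnf152 and Wfdc1 were at least 4.59-fold, 4.29-fold, 3.88-fold and 2.82-fold lower. Several of these signals were close to the floor in the dimmer array. With the floor at the 60th percentile, Klf1, Rnf152, Sars2, Star, Tgfa, Tmem184a, Wfdc1 and Zc3h6 no longer reached 2-fold, each being a bound there. Ccdc182, Msx1, Star and Tgfa were no longer 2-fold apart with the median over each gene's probe sets.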

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

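The liver and red cell tests below were chosen after their values were seen; the trophoblast list was written before its own values were seen, but after Ctsj, Ctsq and Prl2b1. Probe sets with no single gene name took no part in the comparisons, and 4 of them were at least 4-fold higher in the mutant than on the wild-type array. Of these, 3 are unnamed here, with log2 ratios of at least 2.82, of 2.48 and of 2.03 and mutant signals of 169.5, 273.2 and 743.3. Another, shared by the placental prolactin genes Prl2c2, Prl2c3 and Prl2c4 and by Gm7040, had signals of 6.36 and 108.4 and a ratio of at least 2.17. Another 4 unnamed probe sets were at least 4-fold lower, the most changed with signals of 553.5 and 55.0.

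The shared prolactin probe set belongs to a wider pattern, in which some trophoblast, erythroid and leukocyte genes were higher on the mutant array (Ctsj, Ctsq, Prl2b1, Prl7d1, Hemgn, Mpo). Most genes of these lists did not reach 2-fold. Of the measured ones, 1 of 9 trophoblast, 4 of 9 erythroid and 1 of 16 macrophage and leukocyte genes did. Fetal liver carried into the mutant pool is argued against by Afp, with a log2 ratio of -0.47. Alb, with signals of 12.1 and 11.5, was under the floor on both arrays and does not count either way. Apoa2, the other measured liver gene, had a bound of 0.33 that reached 1.08 with a lower floor. For the erythroid part, 3 embryonic globins had a median ratio of 0.18, against 1.22 for the other 6 erythroid genes. This argues against more circulating red cells rich in embryonic globins as the whole cause. Red cells with adult globins are not covered. Hba-a1 (1.87 and 11.7) was under the floor on both arrays, and Hbb-b1 and Hbb-bt had no probe set naming them alone. Probe sets with several gene names took no part, so these values do not show that adult globin was low. The embryonic globins were among the brightest signals, and compression of such signals was not tested. A few placental cells in the mutant pool may account for the trophoblast part. Of the 9 measured trophoblast genes only Prl7d1 was at least 2-fold higher, 2 with the shared Prl2c probe set, while Peg10 was at 26.0 and 28.1. At least 4 were set for carry-over and fewer than 2 against it. Ctsj, Ctsq and Prl2b1 were kept out of this count, with mutant signals of 282.6, 77.7 and 131.9 against 1.29, 0.81 and 0.64. Leaving them out lowers the count, so a low count does not argue against carry-over. The outcome rests on the shared Prl2c probe set. Of the 42 listed genes on the array 9 were measured, 5 of them above the floor on both arrays. The list median of 0.31 ± 0.17 (percentile 99.6) is the ratio of Rhox6, already at 398.9 in wild type, and says little on genes absent there. Placental carry-over therefore cannot be told apart from expression in the complexes. A change of resident macrophages with genotype stays open as untested.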

How the results depend on the processing

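With 1 array per group no replicate could be left out. No paired analysis was possible because each group has 1 array. Centring, quantile and loess normalization gave 104 to 106 higher and 65 lower genes, 104 and 65 of them shared with those reported. The counts of 104 higher and 66 lower genes depend on the floor: 210 and 136 at the 40th percentile, 41 and 33 at the 60th, and 222 and 181 with a pseudocount in place of a floor, which admits genes under the floor on both arrays. The threshold of 3-fold left 22 and 13. Genes with concordant probe sets, 8 higher and 1 lower, became 14 and 6 at the 40th percentile, 5 higher at the 60th, and 4 lower with the pseudocount. Of the 13 lists that stood apart, 6 did so in all 9 alternatives. The GATA and FOG, WNT antagonist, mesonephric, coelomic, endothelial, muscle and hypoxia lists did not in at least 1, the muscle list having too few genes without suffixed probe sets. Of the 14 other lists 11 stayed inside in all 9; the Sertoli, kidney and cholesterol lists stood apart in at least 1. The GATA and FOG median went from 0.22 to 0.11 and the hypoxia median from 0.12 to 0.057 with the median over probe sets. No list that stood apart and no named gene at least 2-fold apart changed sign, but the medians near 0 of the early gonad, WNT feedback, neural, FGF and p53 lists did, as did Actb, Cdh6, Gusb and Lss. Of 243 alternative list medians, 236 moved by less than their bootstrap SD. The meiotic median became -0.15 at the 40th percentile and without suffixed probe sets and -0.17 at the 60th, the kidney median 0.45 at the 40th, the muscle median -0.14 at the 60th and -0.21 with the pseudocount, and the cholesterol median 0.043 without suffixed probe sets. Over a gene's probe sets, the median was -0.13 for Gata4 and 0.77 for Zfpm2. Of 371 alternative values for the 47 named genes at least 2-fold apart, 354 stayed so. Besides the genes lost at the 60th percentile, the median over probe sets ended the 2-fold difference of Ccdc182, Msx1, Star and Tgfa, leaving out suffixed probe sets that of Msx1 and Slc4a1, and the pseudocount that of Alas2, Sp5 and Zfpm1. Other floors and thresholds change how many genes can count; otherwise the cause was not tested. Signal near the floor limits genes such as Star, Klf1 and Akr1c14.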

Other observations

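All tests in this part were chosen after the values they measure were seen. Of the pancreatic genes other than Cpa1, none was measured as 2-fold apart, with Ctrb1 known only as a bound of 0.66. Cela1 had signals of 95.3 and 102.8, Nr5a2 of 67.3 and 66.0, and Ctrb1 of 1.65 and 38.0, with 3 of the 19 listed genes on the array measured and a median log2 ratio of 0.11. Granulocyte genes other than Mpo and Prg2 went both ways, with Ngp at 389.5 and 390.0, S100a8 at 863.3 and 1013, S100a9 at 803.5 and 1054, Prtn3 at 59.5 and 91.7, Cpa3 at 42.6 and 27.6, and Lcn2 at 60.4 and 44.2. None of 10 was 2-fold apart, and their median log2 ratio was 0.09 ± 0.10 (percentile 76.9).

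The lower signals of ovarian supporting cell genes may reflect a loss of that expression program in the mutant, which is a hypothesis from 1 pair of arrays. Less gonad in the mutant complexes is argued against as the whole cause by genes far below the early gonad and germ cell medians. The limit was more than 2 bootstrap SDs of these medians and 2 robust SDs at the gene's own signal. Under it lay 7 of the 16 measured ovarian genes, but 0 germ cell and 0 early gonad genes. Any of 10000 random lists held at most 3 such genes. Those lists were drawn from all measured genes, which less gonad need not lower, so that count does not bear on this cause. Less gonad stays open as a part, as the ovarian list median lay only 1.30 combined SDs below the nearer of these medians. A scaling difference is argued against by the added control RNAs, with a median ratio of 0.0094, but poorer RNA in the mutant pool cannot be told apart, since the 3' to 5' signal ratios of beta-actin and Gapdh were higher in the mutant by 0.19 and 0.29 on the log2 scale. A switch of supporting cells to the Sertoli program is argued against by Sox9 at 0.28 and by 1 of 10 measured testis genes at 2-fold; strain, embryo stage and dissection stay open.

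Cyp17a1, Hsd3b1, Star and Inha were at least 2-fold higher in the mutant, which may reflect steroidogenic expression in the mutant XX gonad. Signal near the floor on the mutant array is argued against for 3 of the 4 genes, which lay above 4 times the floor there, the exception being Star. For Cyp17a1 and Star, under the floor in wild type, that signal over the floor is also the bound itself, so it adds no separate check. Hsd3b1 and Inha were above the floor on both arrays. Adrenal tissue in the mutant pool cannot be told apart from a change in the gonad. Mc2r, with a ratio of 0.32, and Mrap were the only measured genes of the adrenal list. Cyp21a1 (23.8 and 6.67, with 8.85 and 17.5 on its other probe set) and Cyp11b1 (10.3 and 20.8) were under the floor on both arrays. Signals under the floor count neither for nor against adrenal tissue. Trophoblast cells, which can be steroidogenic, cannot be told apart either. On the same array 2 trophoblast genes of the list were at least 2-fold higher, the shared Prl2c probe set included. At least 4 would count for carry-over and fewer than 2 against it. Ctsj, Ctsq and Prl2b1, also high on that array, were kept out of this count.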
